A study of Mus musculus with 4 samples.

How the data were processed

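The series holds 4 two-colour Agilent arrays (mouse) of RNA from intact kidney ureteric buds, with AngII in Cy5 and media in Cy3 on 2 arrays and the dyes swapped on the other 2. Cy dye-labelled cDNA was made from 300 ng of total RNA with a T16N2 primer, read here as oligo-dT, per the labels' protocols. Images were read with Feature Extraction 10.5.1.1, per the file headers, and limma is named without a version in the submitters' processing notes. The deposited intensity values are median pixel intensities of each spot and of its local background, not corrected, and Agilent's processed intensity, which is background-subtracted and dye-normalised per the file headers. The deposited scanner tables also give a log10 ratio of red over green per spot and flags of 0 or 1. The authors' deposited table gives, per spot, a log2 ratio of AngII over media, a mean log2 intensity, an adjusted p-value and a call that works as a score of -1, 0 or 1; its normalisation and design are not given in the sources used here. A further mark in that table, set for 699 spots, has no stated meaning and was not used. The table agrees in direction with the scanner values, with Pearson r = 0.995 across tested features between its log2 ratios and those computed here.

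Ratios were computed in R 4.3.3 with limma 3.58.1. The design had named mean signals, but the files hold median signals, which were used in their place. Background was corrected by normexp with an offset of 50, loess was applied within each array with control spots at weight 0, outlier-flagged spots were left out, saturated spots were kept, and the spots of a probe were averaged. Arrays with AngII in Cy3 were turned, so that each ratio is AngII over media. The 2 arrays of a replicate number were averaged, and the 2 ratios were tested against 0 with lmFit and eBayes at a Benjamini-Hochberg adjusted p under 0.05. A probe was kept if it was well above background in the AngII channel of all 4 arrays or in the media channel of all 4 arrays, which 19393 of 41174 probes were. One probe per gene was used, the brightest, and other tested probes of a gene are given where their log2 ratio differs from it by more than 1.5 times. Names came from accessions matched without versions to RefSeq genes of GRCm38.p6, which named 25097 probes, and other features kept the file's accession. The array annotation is of another build (mm9), so no coordinates are given.

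Before the data were examined, the named genes were fixed by rule: the 12 largest increases and 12 largest decreases past the threshold with one sign on all 4 arrays, passing over accession, clone and numbered placeholder names; 18 genes fixed by name; and up to 4 members with the smallest p in each of 35 gene lists. Egr2, Alas2, Slc4a1 and Car1 fall outside this rule and were named after their values were seen. Genes are grouped by these lists. Lists were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 35 lists, and the estimated correlation and fry were alternatives. Each list's median was also set among 10000 random lists of the same size matched on mean expression in 20 bins, which was chosen after seeing the data, as were the counts by fold size.

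Labels number the AngII and media RNAs 1 and 2, and each array pairs the RNAs of 1 number, so the ratio within an array is the pairing. The labels call them biological replicates without naming separate animals or cultures. On simulated data for this comparison, with array noise as measured over 14995 features, 50 of 50 genes changed by a log2 ratio of 0.50 were recovered, 16 of 14771 unchanged features were called, and the SD ratio of replicates to noise was 1.01. With a simulated spread of 0.1 log2 units between pairs that ratio was 2.16, and 3615 features were called between replicates. Of 50 genes changed by 0.25, 28 were then recovered. The simulation changed only 200 genes and the mitosis list and used the same noise SD for all features. In the data most features passed, so its count of false calls does not carry over to them. All alternatives run are given with their effect in the closing section.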

Results

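Transcripts of mouse kidney ureteric buds, the epithelial outgrowths that branch to form the collecting ducts and ureter, were compared after 6 h with angiotensin II (AngII, 1e-05 M) or with media alone. AngII is the effector peptide of the renin-angiotensin system, and the comparison asks which transcripts differ in intact buds exposed to it. The buds were cultured in matrix gel with 10% serum, 100 ng/ml GDNF and 100 ng/ml HGF. The labels name 2 numbered pairs of AngII and media RNA, and each pair was hybridised to 2 two-colour arrays with the dyes swapped, so that 4 arrays on 1 slide were read. Of 41174 probes, between 19028 and 21922 were well above background in a given channel of a given array. After the filter on dim probes 14995 features were tested, of which 11443 had a gene symbol. The number of arrays limits the precision.

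The log2 ratios of AngII over media of the numbered replicates correlated across features at r = 0.98 (Spearman's rho = 0.97), a description in which features are not independent replicates. The 2 arrays of a dye swap correlated at r = 0.67 and 0.68, and arrays of the same dye orientation at 0.96 and 0.97. The SD across features of the half-difference between the replicates was 0.04 on the log2 scale, and that of the contrast that holds array noise alone was also 0.04, a ratio of 1.02. The AngII over media contrast had an SD of 0.38. In limma, 0 features differed between the replicates at an adjusted p under 0.05, and 771 did at an unadjusted p under 0.05, where chance gives 750. The ratios of the numbered replicates therefore did not differ beyond the array noise. A difference shared by both RNAs of a number cancels in a ratio. The deviations of the replicates from their mean correlated at 0.834 between the AngII and media channels, which are read from the same spots. In the mean log2 intensity of the channels, a comparison chosen after seeing the data, the SD of the half-difference between the replicates was 0.06 and that of the array noise contrast 0.07, a ratio of 0.839. The numbered replicates were counted as 1 independent pair of RNA samples. The limma p-values below measure only the spread between hybridisations of these RNAs. The camera p-values compare list members with other genes within the same ratios. They do not measure how far a shift would recur in other RNA samples. The difference between AngII and media, for genes and for lists, has no check in an independent pair. Values are means over the arrays, as log2 ratios or folds. The range of log2 ratios over the 4 arrays is given for some genes and wherever it is wider than the log2 ratio itself.

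**Figure D1:**
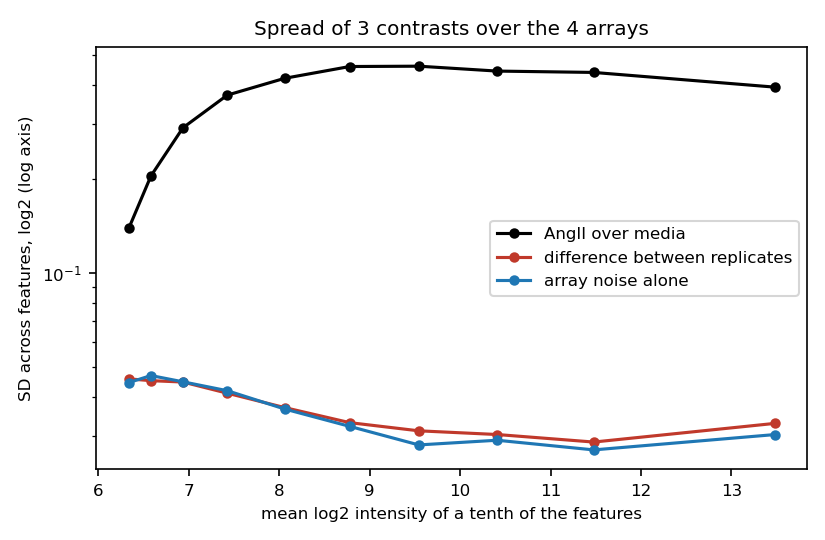
SD across features (log2 units, log axis) of 3 contrasts over the 4 arrays, by mean log2 intensity, with each point 1 of 10 equal bins of the 14995 features. The difference between the replicates was 0.963 to 1.11 times the array noise over the bins, while the AngII over media contrast has a larger SD throughout.

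The 12 largest increases under AngII included 5 globin genes. Hbb-bt rose by a log2 ratio of 2.78 (2.69 to 2.88 over the 4 arrays), and the embryonic globins Hbb-bh1, Hbb-y and Hba-x by 2.58, 2.21 and 1.91. Hba-a1 rose by 2.29. Nts, which encodes the peptide neurotensin, rose by 2.35 (2.18 to 2.53), and Mgp, the matrix Gla protein that restrains calcification, by 2.22 (1.90 to 2.56). Krt20, a keratin of differentiated epithelium, had a log2 ratio of 2.20, the inflammasome adaptor Pycard 2.14 and the mucin Muc20 2.08. Rhcg, an ammonia transporter of the collecting duct, had 1.85 (1.56 to 2.16), and Scnn1g, the gamma subunit of the epithelial sodium channel, 1.83 (1.76 to 1.90). Some globin genes have near-identical copies within their family, so their probes can read more than their own transcript and the split among such copies is uncertain.

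The 12 largest decreases began with Hspa1b and Hspa1a, 2 near-identical genes for the inducible HSP70 chaperone whose probes cannot be fully told apart, which fell by 2.44 (-2.60 to -2.33) and 2.30 (-2.64 to -2.00) on the log2 scale. The chemokine genes Ccl4 and Ccl20 fell by 1.96 and 1.92, Ltb by 1.91 and Tnf by 1.78 (-1.99 to -1.59), the last 2 encoding cytokines of the TNF family. Fjx1 fell by 1.91, Stmn4 by 1.89, the tubulin gene Tuba8 by 1.85, the transcription factor gene Klf13 by 1.79 (-2.26 to -1.35) and Ccdc184 by 1.68. Lars2, the mitochondrial leucyl-tRNA synthetase gene, fell by 1.75, with a wide range over the arrays (-2.75 to -0.91). These 24 genes were selected for passing the threshold with the same sign on all 4 arrays, so neither is a finding about them. The largest limma adjusted p among them was 1.22e-23.

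**Figure D2:**
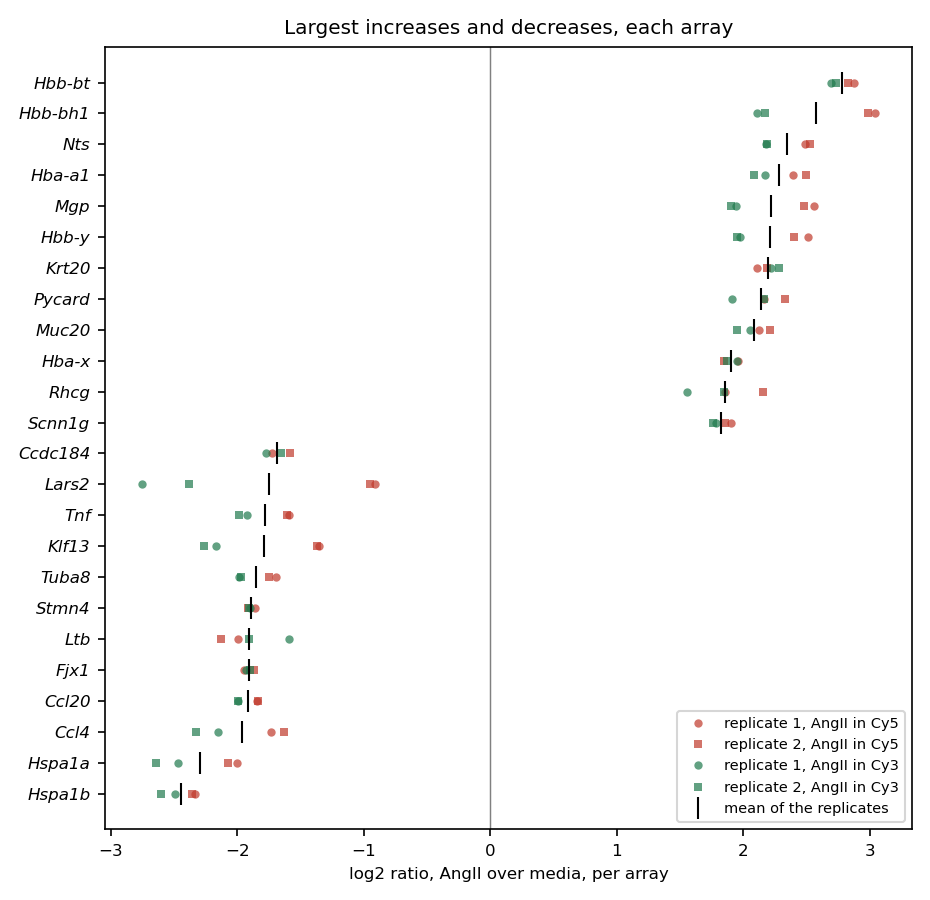
Log2 ratio of AngII over media on each of the 4 arrays for the 12 largest increases and 12 largest decreases. Colour gives the dye of the AngII RNA, shape the replicate number and the bar the mean of the replicates. Hbb-bt lies between 2.69 and 2.88, and Lars2 spreads from -2.75 to -0.91 by dye.

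By size, 318 features differed at least 2-fold, 174 higher and 144 lower under AngII, and 1634 at least 1.5-fold, 824 higher and 810 lower. At an adjusted p under 0.05 in limma, 11588 of 14995 features (77.3%) passed, 5869 higher and 5719 lower. The median absolute log2 ratio over all features was 0.19, and the smallest that passed was 0.07. List members counted below as risen or fallen are those that passed. A list with a like share passing and a near even split does not stand out from all features. With the replicate block as a fixed effect on the 4 arrays, 4641 features passed, and with Agilent's processed signals 1134 features differed at least 2-fold.

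Immediate early genes, which cells induce within minutes of a stimulus, were lower under AngII as a group. Of 27 tested members 22 fell, 4 rose and 1 did not pass, with a median log2 ratio of -0.63 (camera adjusted p = 5.51e-06; adjusted p = 0.768 with an estimated correlation). Dusp1, a phosphatase that switches off MAP kinases, fell by 1.46 (-1.75 to -1.10), Atf3 by 1.31, Klf2 by 1.27 (another probe had -0.64) and Klf6 by 1.00. Egr2 had a log2 ratio of 0.98, Fos -0.18 (-0.21 to -0.13) and Egr1 -0.03 (-0.11 to 0.09), which did not pass. Of 19 tested feedback regulators and targets of ERK, the MAP kinase downstream of growth factor receptors, 14 fell, 1 rose and 4 did not pass, with a median of -0.47 (camera adjusted p = 0.000502; adjusted p = 0.768 with an estimated correlation). The call was lost with the arrays that held AngII in Cy3 alone (adjusted p = 0.0663). Plaur fell by 1.11, Epha2 by 1.01 and Etv4 by 0.95 (-1.28 to -0.66), while Emp1 rose by 0.97. Spry2 fell by 0.70, with -0.17 at another probe, and Spry1 by 0.57, both inhibitors of receptor tyrosine kinase signalling. The list of EGF receptor ligands and receptors had 8 of 10 members lower and none higher, with a median of -0.24 (camera adjusted p = 0.0302, and 0.768 with an estimated correlation). It was led by Nrg1 at -0.48 (-0.84 to -0.08, other probes -0.42 to -0.18), Errfi1 at -0.40, Adam17 at -0.34 (-0.53 to -0.12) and Hbegf at -0.33. Errfi1 and Adam17 encode neither a ligand nor a receptor, so the fall of this list is not one of ligands and receptors alone. Egfr had -0.03 (-0.23 to 0.17) and did not pass, and its other probes lay between -0.02 and 0.69. The call on this list was lost with the mean of a gene's probes (adjusted p = 0.0605), the replicate block (0.0833), and the arrays that held AngII in Cy5 alone (0.105) or in Cy3 alone (0.126). With no filter on dim probes the median of this list was -0.12.

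NF-kB and inflammation genes were lower too, with 17 of 23 tested members that fell, 2 that rose and 4 that did not pass. Their median was -0.64 (camera adjusted p = 5.82e-06, and 0.768 with an estimated correlation), or -0.37 with no filter on dim probes. Beside Ccl20 and Tnf, the NF-kB subunit gene Rela fell by 1.30 (-1.46 to -1.09) and the chemokine gene Cxcl10 by 1.27. Of 17 heat shock genes 13 fell, 3 rose and 1 did not pass, with a median of -0.17 (camera adjusted p = 0.0251; adjusted p = 0.768 with an estimated correlation). The call was lost with processed signals (adjusted p = 0.0666), median centring (0.0823), the mean of a gene's probes (0.0542) and the arrays that held AngII in Cy3 alone (0.166). The median was -0.09 with median centring, -0.26 with the mean of a gene's probes and -0.28 with AngII in Cy5 alone. Hspb8 fell by 1.30 and Cryab rose by 1.02, with 0.19 at its other probe. The median of the heat shock list lay at the 8.86 percentile of 10000 random lists matched on mean expression.

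Genes of S phase and replication fell in 18 of 25 tested members and rose in 3, with a median of -0.23 (camera adjusted p = 0.00356; adjusted p = 0.768 with an estimated correlation). The call was lost with the arrays that held AngII in Cy3 alone (adjusted p = 0.131). The replicative helicase subunits Mcm3 and Mcm5 fell by 0.95 (-1.21 to -0.76) and 0.57, the flap endonuclease gene Fen1 by 0.80 and E2f1 by 0.52 (-0.99 to -0.04). Mitosis genes went both ways, 9 higher and 10 lower of 24, with a median of -0.03 (camera adjusted p = 0.809). Genes of cholesterol synthesis and its regulator SREBP fell in 17 of 24 members and rose in 5, with a median of -0.31 (camera adjusted p = 0.0232; adjusted p = 0.768 with an estimated correlation). The call was lost with the arrays that held AngII in Cy3 alone (adjusted p = 0.166), where the median was -0.16. Srebf2 fell by 0.82 and Fdft1 by 0.62, and Scd2 rose by 0.64.

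Wnt/beta-catenin targets and regulators were higher as a group, with 15 of 23 members that rose, 6 that fell and a median of 0.30 (camera adjusted p = 0.0432; adjusted p = 0.768 with an estimated correlation). Wnt9b and Wnt4, Wnt ligands that act in nephron induction, rose by 1.53 (1.40 to 1.69) and 1.48 (1.41 to 1.54), the feedback inhibitor Nkd1 rose by 1.04, and Wnt7b fell by 1.13. The call was lost with processed signals (adjusted p = 0.0764), median centring (0.0823), the stricter filter (0.0668) and with the arrays that held AngII in Cy3 alone (0.126). The median of the list was 0.62 with processed signals and 0.45 with no background correction.

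Erythroid markers rose in 6 of 7 tested members, with a median of 1.91 (camera adjusted p = 7.89e-05; adjusted p = 0.768 with an estimated correlation), and 0.76 with no filter on dim probes. Adjusted over the list alone, 7 rose, and for the other 34 lists the counts were the same as over all features. Beside the globins, the heme synthesis gene Alas2 had 1.08 and Slc4a1 0.43 (0.19 to 0.63), while Car1 had 0.07 (-0.08 to 0.19) and did not pass over all features. Leukocyte markers, by contrast, had a median of -0.02 with 3 higher, 5 lower and 3 that did not pass (camera adjusted p = 0.934). Ptprc had 0.64, Cd74 0.57, Tyrobp 0.33 and C1qa -0.19 (-0.31 to -0.04). Endothelial markers had a median of -0.09 (adjusted p = 0.633) with Sox18 at 0.49 and Plvap at -0.49, stromal markers 0.09 (0.16), with Acta2 at 1.69 (other probes 0.65 to 1.03) and Cspg4 at 1.07 (another probe 0.66), and neural markers -0.09 (0.401), with Tubb3 at -0.78. Nephron progenitor and mesenchyme markers had a median of 0.00 (0.761), with Tmem100 at 0.77 and Meox1 at -0.60. The stromal list passed with the replicate block (adjusted p = 0.0386) and with no filter on dim probes (0.00736), and its median was 0.06 in replicate 1 and 0.14 in replicate 2.

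Genes of the branching ureteric bud moved in both directions. In the ureteric tip and GDNF/RET list, 11 of 22 members fell, 5 rose and 6 did not pass, with a median of -0.09 (camera adjusted p = 0.183). That median was -0.22 with processed signals and -0.05 with no filter on dim probes. It was -0.04 with AngII in Cy5 alone and -0.18 with AngII in Cy3 alone. Wnt11 fell by 0.50 (-0.74 to -0.27) and the GDNF co-receptor gene Gfra1 by 0.48 (-0.53 to -0.39; another probe had -0.26), and Cyp26b1 rose by 0.58 (0.15 to 1.07). Pax2 had -0.22 (-0.48 to 0.01). Etv5 at 0.05 (-0.06 to 0.15) and Gdnf at 0.00 (-0.11 to 0.13) did not pass, and another Etv5 probe had -0.22. Gdnf, Pax2 and Etv5 lie near background, at mean log2 intensities of 6.30, 6.59 and 6.97. In the bin of dimmest features, at a mean of 6.34, the AngII over media contrast had an SD of 0.14, against 0.46 at 9.54. Small ratios of these dim genes therefore do not show a lack of change. In the ureteric trunk and collecting duct list 14 of 23 members rose and 8 fell, with a median of 0.20 (camera adjusted p = 0.173), which was 0.12 without replicate 1 and 0.07 with no filter on dim probes. Elf5 rose by 1.37 and Gata2 by 0.92. Of 14 sodium and water transport genes 7 rose and 3 fell, with a median of 0.18 (camera adjusted p = 0.101), and Aqp3, a water channel of the collecting duct, rose by 0.88 and Scnn1a by 0.63. In the differentiating nephron list 8 of 12 rose and 1 fell, with a median of 0.17 (camera adjusted p = 0.0988), led by Wnt4, and Pou3f3 had 0.55, with -0.16 at another probe. With the replicate block and the preranked form of camera, the trunk, transport and differentiating nephron lists passed (adjusted p = 0.0387, 0.00362 and 0.0354). With no filter on dim probes so did these 3 (0.0304, 0.0199 and 0.0229) and the tip list (0.0246). The transport list also passed with the arrays that held AngII in Cy5 alone (0.0324).

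Of the renin-angiotensin components, Anpep rose by 0.92 (0.77 to 1.08) and Agtrap, which binds the type 1 angiotensin receptor, by 0.75, with 0.24 to 0.48 at other probes. Lnpep fell by 0.36 (-0.57 to -0.18) and Ace by 0.10 (-0.29 to 0.03), with Ace near background at a mean log2 intensity of 6.69. In all, 3 of 8 tested members rose and 3 fell, with a median of -0.04 (camera adjusted p = 0.94). The receptor genes Agtr1a, Agtr1b and Agtr2, the precursor gene Agt and Ret were not well above background on all 4 arrays in either RNA and were not tested.

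Several other lists did not pass in the main fit but held genes with large ratios. Of 25 genes of ER stress and the amino acid response 13 rose and 8 fell, with a median of 0.34 (camera adjusted p = 0.152), which was 0.09 with no background correction, 0.13 with processed signals, 0.21 with the mean of a gene's probes, and 0.03 and 0.22 with the arrays that held AngII in Cy5 alone and in Cy3 alone. Chac1 rose 2.30-fold, Nupr1 2.27-fold and Trib3 2.38-fold, with a log2 ratio of 0.06 at another Trib3 probe. The TGF-beta and fibrosis list had 11 higher and 8 lower of 21, with a median of 0.16 (adjusted p = 0.364), and Timp1 rose by 1.67, with 0.94 at another probe, and Ltbp2 by 1.37. The hypoxia and glycolysis list had 18 higher and 6 lower of 29 (median 0.17, adjusted p = 0.0774), with Bnip3 at 1.28. In the Notch list 7 of 13 rose and 3 fell (median 0.28, or 0.01 with no filter on dim probes; adjusted p = 0.152), with Heyl at 1.51 and 0.57 at its other tested probe. In the BMP and SMAD list 8 of 15 rose and 4 fell (median 0.11, adjusted p = 0.173), and Bmper rose 2.62-fold, Id2 2.24-fold and Id3 2.15-fold. The retinoic acid list had 7 higher and 5 lower of 17 (median 0.02, adjusted p = 0.633), with Aldh1a1 at -1.56 and Aldh1a3 at 1.08. The median of that list turned sign between the replicates, 0.08 in replicate 1 and -0.03 in replicate 2. With the replicate block the BMP, TGF-beta, Notch and hypoxia lists passed (adjusted p = 0.0173, 0.0230, 0.0354 and 0.0386), and with no filter on dim probes so did these (0.0199, 0.0424, 0.0199 and 0.00324) and the ER stress list (0.00725). With the arrays that held AngII in Cy5 alone the BMP (0.0305) and Notch (0.0385) lists passed, and the hypoxia list passed with median centring (0.0249) and with AngII in Cy3 alone (0.0420).

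**Figure D3:**
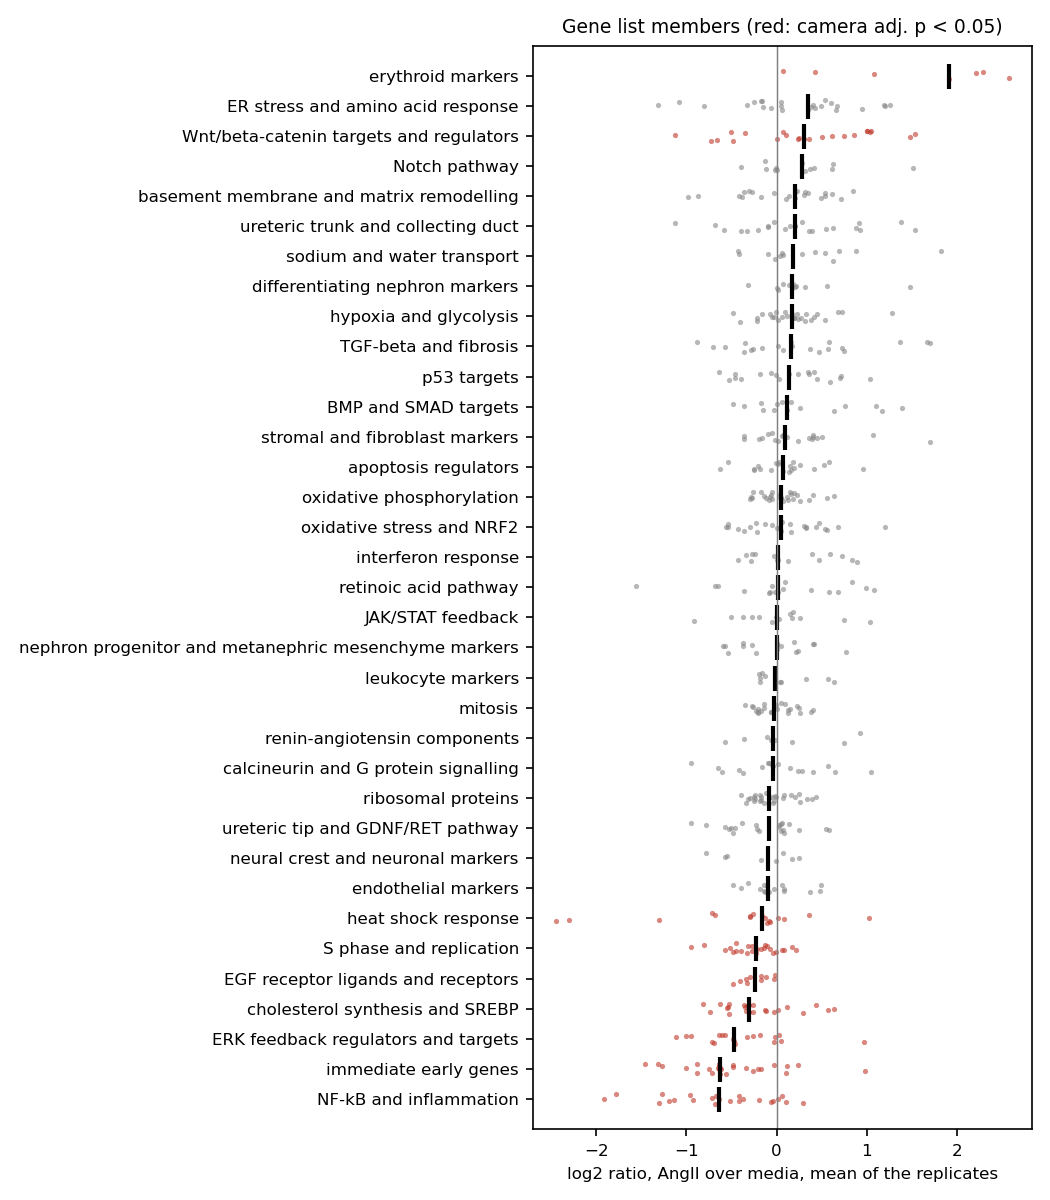
Log2 ratio of AngII over media for the tested members of 35 gene lists, one point per gene as the mean of the replicates, with a bar at each median. The 9 lists in red had a camera adjusted p under 0.05, with medians from -0.64 for NF-kB and inflammation to 1.91 for erythroid markers.

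The remaining 9 lists were matrix remodelling, p53 targets, interferon response, apoptosis, oxidative phosphorylation, oxidative stress, ribosomal proteins, calcineurin and G protein signalling, and JAK/STAT feedback. Their medians ran from -0.09 for ribosomal proteins to 0.20 for matrix remodelling, and camera adjusted p from 0.439 to 0.992. With the arrays that held AngII in Cy5 alone and in Cy3 alone the medians were 0.14 and -0.23 for ribosomal proteins and 0.02 and 0.35 for matrix remodelling. Within them Gsta3 was 2.30-fold higher, with a log2 ratio of 0.60 at another probe, and log2 ratios were 1.05 for Itpr3, 1.04 for Ccng1, 1.03 for Osmr (another probe 0.36), -0.99 for Plau, -0.95 for Rcan1 (another probe -0.11) and 0.89 for Psmb8. The leukocyte and renin-angiotensin lists had medians below 0 while camera gave their direction as up, and the nephron progenitor list had a median of 0.00 with camera direction down, so these 3 lists have no settled sign.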

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

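The test of whether both replicate numbers rest on the same RNA, the test with median centring and the comparison of mean intensity were chosen only after the result was seen, and a low ratio was left undecided in the first although it met the bound written for that cause. The ratio of AngII over media differed between the 2 dye orientations for 8528 of 14995 features in limma with a dye term, and 2989 of them had one sign on both arrays of one orientation and the opposite sign on both arrays of the other, which is a difference between array orientations of the same RNAs. Averaging both orientations cancels a dye effect of this kind.

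The numbered replicates differed no more than repeat arrays do. The SD of their half-difference was 1.02 times that of array noise, where a simulated spread of 0.1 log2 units between pairs gave 2.16. Shrinkage by background correction is argued against, since the ratio was 0.996 with no background correction and 1.01 with processed signals. With median centring in place of loess the ratio was 0.836. There the SD of array noise rose from 0.037 to 0.050 and that of the replicate half-difference from 0.038 to 0.042. The lower ratio thus came from a larger noise term and cannot decide whether loess shrank a difference. A difference shared by both RNAs of a number cancels in a ratio, and the replicates differed in mean intensity by 0.839 times the array noise. The same RNA or a split pool behind both numbers, and 2 cultures that scarcely differed, cannot be told apart, since both give a ratio near 1. No biological explanation was tested.

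Globin transcripts were higher under AngII, with log2 ratios from 1.91 to 2.78 over 5 genes. Whether blood as a whole was higher in the AngII RNA stays open: 11 leukocyte markers had a median of -0.021, but they went both ways, from -0.19 to 0.64, and several lie near background (C1qa at a mean log2 intensity of 6.44, Ptprc at 6.50), so the bound on the median set in advance against this explanation excludes nothing. More red cells or their precursors may account for it, but the erythroid genes other than globins gave a median of 0.43 over 3 tested genes, between the bounds set in advance, so this cannot be told apart from a change within erythroid cells. An effect of AngII itself stays open, as untested.

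Hspa1a and Hspa1b were lower under AngII. A handling stress that was stronger in the media RNA is a candidate explanation: it predicted a median under -0.5 for the immediate early genes, which had -0.63, although Fos at -0.18 and Egr1 at -0.03 were near 0. The other 15 heat shock genes had a median of -0.13, between the bounds set in advance for cross-hybridisation between the near-identical probes alone. That test does not bear on cross-hybridisation. It can blur which of the near-identical transcripts fell, but does not by itself give a lower signal at both probes. AngII and handling are confounded, with 1 independent pair, and an effect of AngII itself stays open, as untested.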

How the results depend on the processing

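The count by fold size, the random lists, median centring for the replicate correlation and the fixed replicate block with a dye term were chosen only after the data were seen. The 11588 features past the threshold were 4641 with the replicate block as a fixed effect and 6568 with 4 arrays and no replicate block. Both of these leave the dye effect in the residual. The count was 7447 with single channels unpaired and 1634 with a 1.5-fold minimum. The single-channel fit drops the pairing within an array. It leaves in the residual the variation shared by the AngII and media channels, whose deviations correlated at 0.834. The random replicate block gave 11728, with a consensus correlation of -0.85 between the dye-swapped arrays of a pair, and the fixed block with a dye term 11415; a random block beside a dye term could not be fitted on 4 arrays. The other 13 alternatives stayed within 1.5 times the main count. The 318 features at least 2-fold apart were 1134 with processed signals and 496 with an offset of 16, and lay between 316 and 329 leaving out either replicate. The 9 lists past the threshold were 19 with no filter, 16 with the replicate block and 4 with the arrays holding AngII in Cy3. They were 0 with an estimated correlation, 28 with fry and 14 by random lists. The random lists left out the heat shock list. They took in the trunk, matrix remodelling, Notch, ER stress, hypoxia and transport lists, which did not pass by camera in the main fit. Fry does not compare a list with other genes. The test with an estimated correlation rests on 1 residual degree of freedom. That estimate was 0.08 for immediate early genes and below 0 for the other lists past the threshold, so there a higher correlation did not remove the call. The replicate block setting also changed the list statistic, to the preranked form of camera. No cause of the other shifts was tested. Immediate early, NF-kB and erythroid lists passed in each other setting that tests lists by camera or its preranked form at the preset correlation. Pearson r between the replicates stayed within 0.05 of 0.98, a bound set after these values were seen, but Spearman's rho fell from 0.965 to 0.732 with no filter on dim probes. Counting a change of sign where a gene passed the threshold in the main fit or in the alternative, and without a test only where it passed in the main fit, named genes turned sign in 5 cases: Ace to 0.0077 and Egfr to 0.16 with AngII in Cy5 alone, Jag1 to -0.031 with AngII in Cy3 alone, and Etv5 to -0.085 and Egfr to 0.20 with the mean of a gene's probes. The authors' deposited table called 10510 of the tested features, 10329 of them also called here with one sign. Signal over background limits the dim features.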

Other observations

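The genes in this part were chosen after their values were seen. Of 25 tested histone genes with an H1f, H2ac, H2bc, H3c or H4c symbol 21 fell and 4 rose, with a median log2 ratio of -0.43, a count on genes picked for this pattern. H1f4 had -1.58 (-1.82 to -1.39 over the 4 arrays), H4c14 -1.41, H4c4 -1.35, H4c6 -1.34 and H1f5 -1.16 (-2.06 to -0.28), while H2bc21 had 0.45 and H1f2 0.44 (0.17 to 0.69). The median was -0.44 with no background correction and with processed signals, -0.35 with median centring and -0.44 with an offset of 16. Histone genes are near-identical copies in part, so the split among them is uncertain, and the labelling primer is read here as oligo-dT, while most histone transcripts lack a poly(A) tail.

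Further single genes outside the lists had large ratios. Fxyd4, a regulator of the sodium pump, was 2.82-fold higher, and log2 ratios were 1.39 for the potassium channel gene Kcnj16 and 1.23 for the urea transporter gene Slc14a2, with 0.12 at another Slc14a2 probe. Spp1, which encodes osteopontin, had 1.71 and Igfbp7 1.46. On the lower side Csrp1 had -1.62, the tubulin gene Tubb2a -1.17 (other probes -0.88 and -0.63) and the actin gene Actg1 -1.15 (another probe -0.68).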
